A study of Mus musculus with 6 samples.

How the data were processed

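RNA from the striatum of 3 mice lacking PGC-1alpha and 3 wild-type littermates, all female and 6 months old, was hybridised to Affymetrix mouse arrays, 1 array per mouse. Per the labels, RNA was isolated with Qiagen RNeasy columns and labelled with biotin, and the null and wild-type mice came from crosses of heterozygous founders. The series design gives total RNA for all 6 mice, but the label of KO 3 reads cytoplasmic RNA while the other 5 read total RNA. The sources used here do not settle which holds, so KO 3 was kept and results without it are given. Genotype and replicate number were taken from the sample titles. The replicates are separate mice, so the spread between arrays holds both biological and technical variation.

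The deposited values are intensity values on a linear scale, 1 signal per probe set and array, summarised with MAS5 per the submitters' processing notes. The MAS5 version, the target value and the software settings are not given in the sources used here. The deposited intensity values were already scaled: the mean without the lowest and highest 2% of values was 149.96 on all 6 arrays, and the medians ran from 43.1 to 47.3. Scaling of this kind removes any difference in total RNA between groups, so every change below is relative to the rest of the array. Detection calls and probe-level values were not used here. The number of arrays, 3 per group, limits the precision of each value.

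Of the 45101 probe sets, 64 were Affymetrix controls and were left out of the tests. The platform annotation listed 35877 probe sets, 34945 with exactly 1 gene symbol and 932 with several, and 9160 were not listed and stay unnamed here. Of those with 1 symbol, 34741 matched a gene of the GRCm38.p6 assembly table, which was used for current names and for which genes are neighbours. Outdated symbols were updated through that table. The array annotation names no genome build, so no coordinates are given.

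Signals were transformed to log2 after adding 16, and fold changes refer to that scale, which understates the change of dim probe sets. Probe sets at or below the 40th percentile of mean log2 signal over all 6 arrays, a signal of about 26.8, were left out, which left 27022 probe sets and 12323 named genes. Differences between KO and WT were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, prior degrees of freedom 8.34) and adjusted by Benjamini-Hochberg over all probe sets tested. The threshold was an adjusted p under 0.05. Single values were also described with a two-sided exact permutation test, which cannot go below 0.1 for 3 mice against 3.

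A total of 31 gene lists were fixed, covering mitochondria, metabolism, cell types, neighbouring regions, stress responses and housekeeping. They held 571 symbols, of which 495 were tested. Each gene entered once, by its brightest tested probe set. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 31 lists, with camera at an estimated correlation and limma's fry as alternatives. Members were also adjusted over the list alone. The groups, the tests, the lists, the rule for naming genes and the alternatives were chosen before the data were examined.

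The genes named are the probe sets of Ppargc1a, the 12 genes with the largest rise and the 12 with the largest fall among called probe sets whose groups did not overlap, and for each list its called members or, without any, the 2 members with the smallest p. Other genes are said to be chosen after their values were seen, or are given as further members of a list. Control probe sets for GAPDH and beta-actin gave 3'/5' ratios as a measure of RNA integrity.

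The alternatives were quantile normalization, centring each array on its median, an offset of 1 or 64, no filter or a filter at the 60th percentile, eBayes without trend or with robust estimation, a plain equal-variance test per probe set, the replicate number as a block, an adjusted p under 0.1, the mean of a gene's probe sets, and leaving out each array in turn. A further alternative, without genes near clustered calls, was added after seeing the data. The procedure was tested on simulated data with the same 27022 probe sets and 200 changed ones per simulation. The test called 19.8% of probe sets changed by 0.5 on the log2 scale, 64.8% of those changed by 1, 88.2% of those changed by 1.5 and 93.4% of those changed by 2. Of all simulated calls, 3.59% were unchanged probe sets, and with no change at all there were 0.1 calls per simulation. A simulated list, complex I, lowered by 0.2 on the log2 scale was called in 100% of the simulations. Simulated noise was independent between probe sets, whereas the estimated inter-gene correlation of complex I in the real data was 0.075. The simulations therefore do not show how the list tests behave when members are correlated.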

Results

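Gene expression was profiled in the striatum of mice lacking PGC-1alpha, a transcriptional coactivator of genes for mitochondria and oxidative metabolism encoded by Ppargc1a, and in wild-type (WT) littermates. Each genotype had 3 female mice aged 6 months, with 1 Affymetrix array per mouse. The knockout (KO) mice were compared with the WT mice. Signals on the 6 arrays correlated at 0.980 to 0.983 among KO mice, at 0.977 to 0.978 among WT mice and at 0.975 to 0.978 between the genotypes. RNA integrity was alike in both groups. The log2 ratio of 3' to 5' signal was -0.453 ± 0.010 (SD, n = 3) for GAPDH in KO and -0.453 ± 0.036 in WT (exact permutation p = 1). For beta-actin it was 1.11 ± 0.066 in KO and 1.14 ± 0.10 in WT (exact permutation p = 0.8), and the ranges overlapped for both.

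Ppargc1a transcript was lower in all 3 KO mice than in any WT mouse, for all 5 of its probe sets. The one with the largest change read 82 ± 12 in KO and 357 ± 47 in WT (SD, n = 3). The KO minus WT difference was -1.93 (SE 0.14) on the log2 scale, with a limma adjusted p of 3.0e-05. Over the 5 probe sets the decrease ran from 2.17-fold to 3.81-fold, and each passed the threshold. All 5 calls held without any 1 array, and the leading difference then ran from -2.04 to -1.83. Without the intensity trend 2 of the 5 were lost (adjusted p = 0.087 and 0.12; over all alternatives these ran from 0.0049 to 0.40 and from 0.0019 to 0.41). An exact permutation test of this value gave p = 0.1, the smallest that 3 against 3 allows. Which part of the gene was altered, relative to the probe sets, is not given in the sources used here, so the signal left in KO mice cannot be read as intact transcript.

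**Figure D1:**
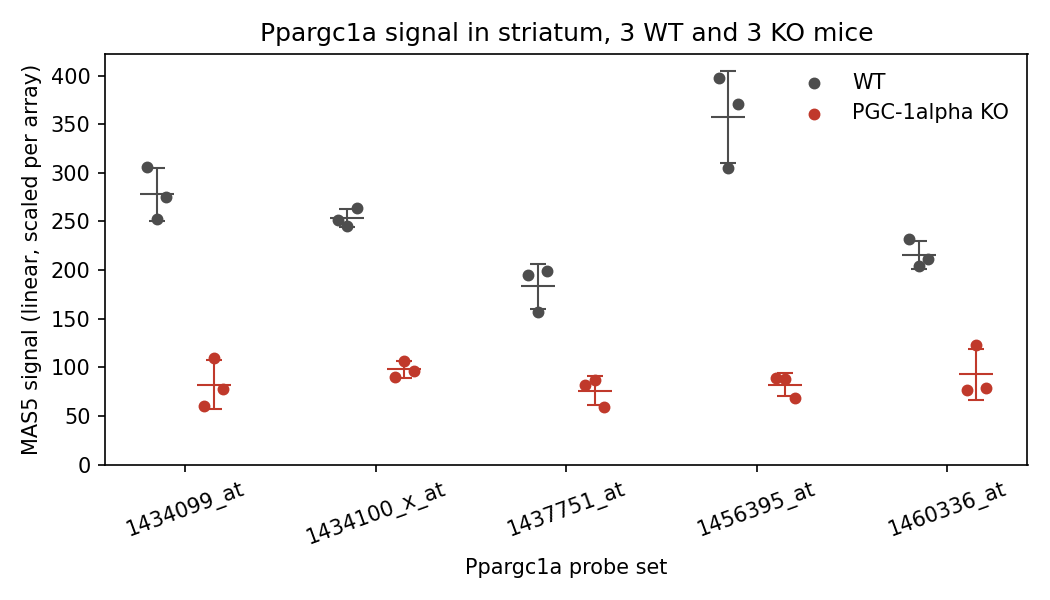
Signal of the 5 Ppargc1a probe sets (MAS5 signal, linear scale) in each WT mouse (grey) and KO mouse (red), with horizontal lines for the mean and bars for the SD of 3 mice. For the probe set with the largest change the WT mice read from 305 to 397 and the KO mice from 68.4 to 89.5, and no KO point reaches a WT point of the same probe set.

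The KO striatum differed from WT in a modest number of transcripts, and 122 of the 127 called probe sets belong to other genes than Ppargc1a. At an adjusted p under 0.05 in limma, 48 probe sets were higher in KO and 79 were lower, from 83 named genes, 31 of them higher and 55 lower. Adi1, Pdxdc1 and Sox11 are counted in both directions because their probe sets disagreed. Of the called probe sets 21 had no gene name or several. All 127 showed no overlap between KO and WT, which a call at this threshold all but requires. Of the 27022 tested, 14.4% showed no overlap, where chance gives 10%. Higher probe sets made up 37.8% of the calls, and 50.9% when each array was centred on its median. Without KO 1 the total was 65 calls, without KO 2 it was 73 and without WT 2 it was 70. Without KO 3, whose label names cytoplasmic instead of total RNA, it was 87. Without the intensity trend 25 of the 127 remained called, and a plain equal-variance test per probe set called 0, with 2247 at an unadjusted p under 0.05 against 2478 in limma.

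The largest rise was in Rps9, which encodes a protein of the small ribosomal subunit. One of its probe sets read 876 ± 39 in KO and 111 ± 15 in WT (SD, n = 3; difference 2.82, SE 0.11, adjusted p = 7.8e-08). The other Rps9 probe sets differed by only -0.01 and -0.09 and did not pass, so the rise belongs to that probe set and not to the gene as a whole. Cdhr1, a cadherin-related protein of photoreceptors, rose from 47.5 ± 13 to 388 ± 8.3 (difference 2.69, SE 0.15). Pam, which amidates neuropeptides, rose from 112 ± 0.93 to 581 ± 163 (difference 2.18, SE 0.17). Fam241a rose by 1.83 (SE 0.15) and Sdc4, a cell-surface heparan sulphate proteoglycan, by 1.33 (SE 0.11), although a second Sdc4 probe set differed by -0.06. A second Fam241a probe set, brighter in WT, gave 0.62 and did not pass. Gnb1, a G-protein beta subunit, rose in both probe sets tested, by 1.25 and 0.90. Wdfy1, an endosomal protein, rose in 3 probe sets, by 1.17, 1.20 and 1.27. A Mapk8 probe set for the stress kinase JNK1 rose by 1.16, while its other probe sets ran from -0.72 to 0.08 and did not pass. Adi1, an enzyme of methionine salvage, gave 1.17 by its leading probe set and -1.08 by another, both called. The remaining rises were Pisd-ps3, a pseudogene (2.21, SE 0.39), Mxra8 (1.05, SE 0.20) and Ramp1, which escorts calcitonin-family receptors (0.93, SE 0.17). The Pisd-ps3 probe set lay below the filter signal of 26.8 in WT (6.8 ± 1.8) and was uneven in KO (65, 219 and 44.8), so the size and rank of this rise depend on the offset. Other Ramp1 probe sets differed by 0.12 and -0.22 without passing.

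Among the falls, Pdxdc1, a pyridoxal-dependent decarboxylase domain protein, lost nearly all signal of 1 probe set. It read 11.4 ± 7.8 in KO and 241 ± 20 in WT (SD, n = 3; difference -3.27, SE 0.22, adjusted p = 1.7e-05), while another for the same gene was called higher, by 0.93. Ghitm, a protein of the mitochondrial inner membrane, fell in both of its probe sets. Signals for the leading one were 777 ± 27 in KO and 2432 ± 175 in WT (difference -1.62, SE 0.08, adjusted p = 5.1e-07), and the second Ghitm probe set differed by -0.66. Efhd2, a calcium-binding protein, differed by -1.60 (SE 0.20) and Vamp3, a vesicle SNARE of endosomes, by -1.36 (SE 0.13). A second Efhd2 probe set gave -0.41 and did not pass. Other Vamp3 probe sets ran from -0.66 to 0.03 and did not pass. Slc2a5, a fructose transporter, differed by -1.68, Ldb3, a Z-disc protein of muscle, by -1.67, Pithd1 by -1.55 and Pde6h, a phosphodiesterase subunit of cones, by -1.49. These 4 probe sets read between 61.8 and 76.2 in WT. Their KO means and that of Pdxdc1 lay below the signal of 26.8 used as the filter, so the sizes and ranks of these 5 falls depend on the offset. Second probe sets for Ldb3 (-0.25) and Pithd1 (-0.26, the brighter of its probe sets) did not pass. Lactb, a mitochondrial filament protein, differed by -1.09 (SE 0.17). Sox11, a transcription factor of developing neurons, gave -1.25 by its leading probe set and 0.73 by another, both called. Mapk14, the p38alpha kinase, gave -1.25 by its leading probe set, while its other 4 probe sets ran from -0.04 to 0.28 and did not pass.

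Of these 24 genes, Ppargc1a, Rps9, Cdhr1, Pam, Fam241a, Sdc4, Gnb1, Adi1, Mapk8, Pdxdc1, Ghitm, Efhd2, Vamp3 and Sox11 stayed past the threshold without any 1 array. The others lost it without at least 1 array. Ramp1 was lost without any 1 of the 6 (adjusted p up to 0.17), Mxra8 without any but WT 1 (0.18), Pithd1 without any but KO 2 (0.13) and Mapk14 without any but KO 3 (0.17). Pisd-ps3 was lost without KO 1 or any WT array (up to 0.11) and Slc2a5 without KO 1, KO 3, WT 2 or WT 3 (0.11). Wdfy1 was lost without KO 1, KO 2 or WT 3 (0.092), Pde6h without KO 1, WT 2 or WT 3 (0.062), Lactb without KO 2, WT 1 or WT 3 (0.064) and Ldb3 without WT 3 (0.064). No filter ended the calls of these 10 (adjusted p from 0.069 to 0.17). Without the intensity trend all of them but Pde6h were lost, and so were Efhd2 (0.14), Gnb1 (0.15) and Sox11 (0.061), while the plain equal-variance test ended all 24. The replicate block ended the call for Ramp1 (0.080), and leaving out genes near clustered calls ended those for Ramp1 (0.059) and Pisd-ps3 (0.051). Robust estimation ended the calls for Pisd-ps3 (0.077), Efhd2 (0.085) and Mapk14 (0.053). An offset of 1 ended those for Mxra8 (0.061), Slc2a5 (0.065) and Mapk14 (0.063), and an offset of 64 that for Pisd-ps3 (0.089). Over all alternatives, among them the plain equal-variance test, the adjusted p ran from 0.018 to 0.50 for Pisd-ps3, from 0.0050 to 0.48 for Mxra8 and from 0.0077 to 0.44 for Slc2a5. It ran from 7.2e-04 to 0.43 for Efhd2, from 0.0041 to 0.50 for Mapk14, from 1.9e-05 to 0.43 for Gnb1, from 0.0030 to 0.38 for Sox11 and from 0.026 to 0.34 for Ramp1. Cdhr1, Ghitm, Sdc4, Gnb1, Mxra8, Adi1, Sox11, Mapk8, Ldb3, Mapk14, Efhd2, Slc2a5 and Vamp3 have another called gene as neighbour. What is said of such genes near the end applies to them.

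Genes of the mitochondrial respiratory chain were lower in KO striatum as a group, each by a small amount. Pooled over complexes I to V, 78 of 80 genes measured were lower, with a median of -0.18 on the log2 scale (SE 0.032 over arrays), a signal 11.9% lower. The per-mouse medians relative to the WT mean were -0.17, -0.20 and -0.17 in KO and 0.02, 0.04 and -0.06 in WT. None of the 80 genes passed adjustment over all probe sets in limma, and 46 had an unadjusted p under 0.05. The exact permutation p of the per-mouse medians was 0.1, the smallest possible. By limma's camera, 18 of the 31 gene lists were called at the preset correlation, 10 lower and 8 higher, but 0 were called with an estimated correlation. Fry called 7, namely complexes II and III, complex V, complex I, fatty acid oxidation, cholesterol synthesis, dopaminergic afferent and circadian clock. Without KO 3 the lists of complexes I to V stayed called.

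Complexes II and III, succinate dehydrogenase and cytochrome bc1, had the lowest median among the chain lists. All 14 genes were lower (median -0.27, camera adjusted p = 2.3e-13, adjusted p = 0.12 with an estimated correlation). Over all probe sets 0 passed, and 11 passed when adjusted over the list alone. Sdhb read 1450 ± 90 in KO and 1827 ± 68 in WT (difference -0.33, SE 0.07, adjusted p = 0.091), and Uqcrh differed by -0.29 (adjusted p = 0.087). Both passed only after quantile normalization (adjusted p = 0.0497 for each; up to 0.44 for Uqcrh and 0.42 for Sdhb over all alternatives). The ATP synthase list, complex V, was called lower with all 16 genes lower (median -0.21, camera adjusted p = 2.3e-13, adjusted p = 0.15 with an estimated correlation). No member passed over all probe sets, and 14 did adjusted over the list alone. Atp5pb read 4159 ± 79 in KO and 5077 ± 90 in WT (difference -0.29, adjusted p = 0.075), and Atp5g1 differed by -0.31 (adjusted p = 0.10). Complex I, NADH dehydrogenase, was called lower with 33 of 34 genes lower (median -0.15, camera adjusted p = 1.3e-11, adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone 4 passed, and over all probe sets 0. Ndufc1 gave -0.27 and Ndufb8 -0.26 (adjusted p = 0.19 for each). Complex IV, cytochrome c oxidase with its assembly factors, was called lower with 15 of 16 genes lower (median -0.17, camera adjusted p = 4.4e-05, adjusted p = 0.18 with an estimated correlation). None passed over all probe sets, and 5 passed adjusted over the list alone, Cox6c (-0.25) and Cox5a (-0.22) leading.

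**Figure D2:**
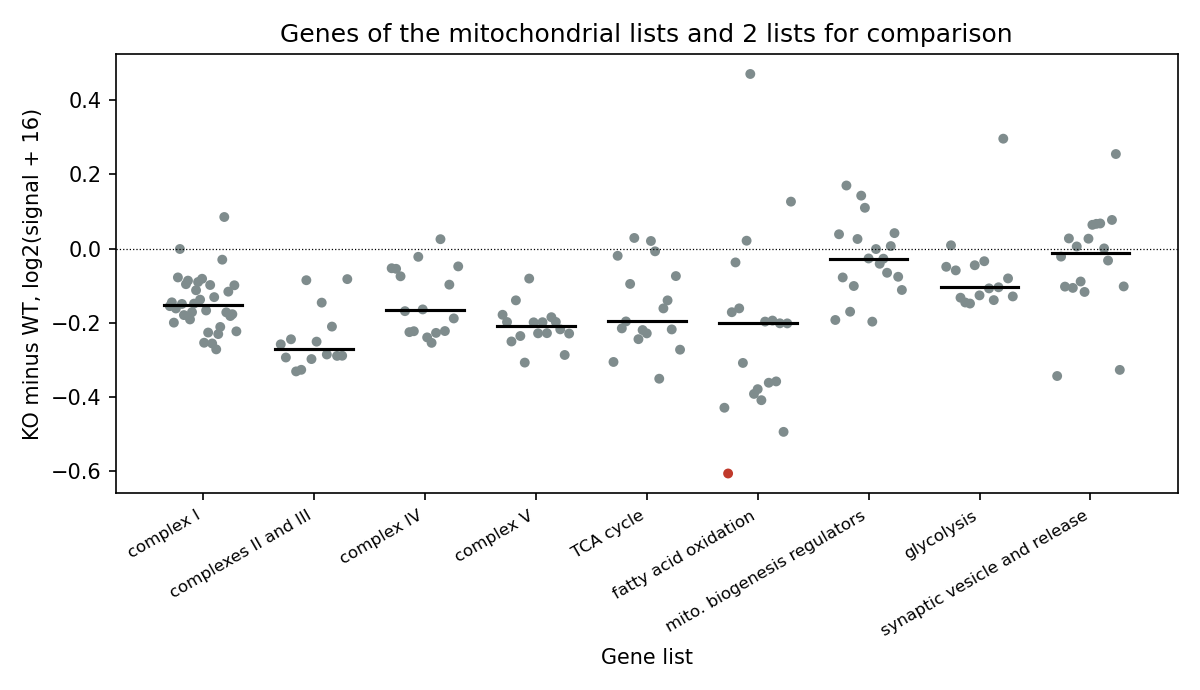
KO minus WT difference of log2(signal + 16) for each measured gene of complexes I to V, the TCA cycle, fatty acid oxidation and the biogenesis regulators, with glycolysis and synaptic vesicle genes beside them, 1 point per gene and a line at each list's median. Red marks the only gene shown whose brightest probe set was called, Acadl at -0.61. The medians of complexes II and III, complex V and complex I lie at -0.27, -0.21 and -0.15, and those of the biogenesis regulators and the synaptic vesicle genes at -0.03 and -0.01.

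Fatty acid oxidation and the TCA cycle, which feed the chain, were called lower by camera as lists, and so were glycolysis and cholesterol synthesis. Fry called fatty acid oxidation and cholesterol synthesis, but not the TCA cycle (adjusted p = 0.068) or glycolysis (0.24). In fatty acid oxidation 16 of 19 genes were lower (median -0.20, camera adjusted p = 1.1e-07, adjusted p = 0.11 with an estimated correlation). Acadl, the long-chain acyl-CoA dehydrogenase, fell from 349 ± 18 to 224 ± 22 (SD, n = 3; difference -0.61, SE 0.10, adjusted p = 0.027). Acadl was the only member called by its brightest probe set, and 8 passed adjusted over the list alone. Hadhb, a subunit of the trifunctional protein, was called lower by a dimmer probe set (-0.46, adjusted p = 0.039). The Acadl call was lost without KO 2, KO 3, WT 2 or WT 3 (adjusted p up to 0.13), with no filter (0.067), without the intensity trend (0.21) and with the replicate block (0.064). Over all alternatives its adjusted p ran from 0.023 to 0.38. The TCA cycle list was called lower with 15 of 17 genes lower (median -0.20, camera adjusted p = 1.9e-06, adjusted p = 0.18 with an estimated correlation). Adjusted over the list alone 5 passed, and over all probe sets 0. Pdha1, a subunit of pyruvate dehydrogenase, gave -0.35 (adjusted p = 0.066, with 0.038 after quantile normalization and 0.038 to 0.40 over all alternatives), and citrate synthase, Cs, gave -0.31 (adjusted p = 0.094). Glycolysis had 13 of 15 genes lower (median -0.10, camera adjusted p = 0.016, adjusted p = 0.34 with an estimated correlation) and 0 passing over all probe sets or over the list alone. Ldhb gave -0.15 and the glucose transporter gene Slc2a1 0.30, neither passing. The per-mouse medians of KO and WT overlapped, and without WT 2 the list median was -0.06. The glycolysis call was lost without KO 1, KO 2 or WT 2 (adjusted p up to 0.15), with each array centred on its median (0.11), without the intensity trend (0.087) and with the mean of a gene's probe sets (0.12), and over all alternatives the adjusted p ran from 0.0027 to 0.15. Cholesterol synthesis had 15 of 17 genes lower (median -0.15, camera adjusted p = 0.0096, adjusted p = 0.17 with an estimated correlation). None passed over all probe sets, and 1 passed adjusted over the list alone, Hmgcs1 (-0.31), with Nsdhl next at -0.25. That call was lost without WT 1 (adjusted p = 0.054).

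The list for mitochondrial biogenesis was not called (19 genes, median -0.03, camera adjusted p = 0.78). Its members include Tfam, Nrf1, Esrra and the related coactivator Ppargc1b, and also import and mitochondrial DNA proteins such as Tomm20 and Polg. None had an unadjusted p under 0.05 in limma or passed adjusted over the list alone. Sirt3 gave -0.20 and Esrra -0.19, both with overlapping groups. The list for defence against reactive oxygen species was not called either (17 genes, median -0.04, adjusted p = 0.16). In it Sod2, the mitochondrial manganese superoxide dismutase, fell from 745 ± 11 to 556 ± 22 (SD, n = 3; difference -0.41, SE 0.08, adjusted p = 0.039). It was the only member called over all probe sets, and 2 passed adjusted over the list alone. The Sod2 call was lost without any 1 array (adjusted p up to 0.16) and with each array centred on its median (0.11). No filter (0.074), no intensity trend (0.29), the replicate block (0.098) and leaving out genes near clustered calls (0.059) also ended it, and over all alternatives the adjusted p ran from 0.030 to 0.29.

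The list of genes known to depend on PGC-1alpha in inhibitory neurons was called lower by camera at the preset correlation, and not by fry (adjusted p = 0.069). All 11 measured were lower (median -0.34, camera adjusted p = 1.1e-07, adjusted p = 0.17 with an estimated correlation). The WT mice differed on this list, with medians of 0.23, -0.07 and -0.09 against -0.33, -0.27 and -0.37 in KO mice, and without WT 1 the list median was -0.18. The list was drawn from knowledge of PGC-1alpha in other brain regions, not from these mice, and it shares Idh3a and Atp5o with the lists above. Phyh, a peroxisomal enzyme that breaks down phytanic acid, fell from 416 ± 25 to 198 ± 24 (SD, n = 3; difference -1.02, SE 0.11, adjusted p = 7.9e-04). It was the only member called over all probe sets, held without any 1 array, and 6 passed adjusted over the list alone. Of these, Syt2, a calcium sensor for fast transmitter release, gave -0.78, Pvalb, the calcium buffer parvalbumin, -0.64 and Cplx1, a complexin, -0.34. Pvalb signal was 476, 748 and 444 in KO mice and 1362, 652 and 701 in WT mice, so the groups overlapped.

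Marker lists for the main neuron types of the striatum had small medians, while single members moved more, in both directions. For medium spiny neurons, the projection neurons, 17 of 22 genes were higher (median 0.07, camera adjusted p = 0.0096, adjusted p = 0.66 with an estimated correlation), and 0 passed over all probe sets or over the list alone. Gpr6 gave 0.30 and Adcy5 0.20. The per-mouse medians overlapped, and the list median was 0.04 without KO 1, 0.02 without WT 3 and 0.12 without WT 2. That call was lost without KO 1, WT 1 or WT 3 (adjusted p up to 0.35). Striatal interneuron markers were not called (14 genes, median 0.07, adjusted p = 0.32), with Kit at 0.43 and Pvalb at -0.64 and 0 passing over all probe sets or over the list alone. Synaptic vesicle genes (18 genes, median -0.01, adjusted p = 0.50) and axon, cytoskeleton and channel genes (18 genes, median -0.04, adjusted p = 0.81) were not called, and no member passed by either adjustment. Cplx1 at -0.34 and Vamp1 at -0.33 led the first, and Ina at 0.20 and Map1b at 0.21 the second. Without KO 3 the synaptic vesicle list was called lower (median -0.05, adjusted p = 0.049, with 0.049 to 0.97 over all alternatives).

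Among glia, the oligodendrocyte and myelin list was called lower, with 16 of 21 genes lower (median -0.17, camera adjusted p = 0.0096, adjusted p = 0.55 with an estimated correlation). None passed over all probe sets. Adjusted over the list alone 1 passed in each direction, Mag, the myelin-associated glycoprotein, at -0.43 and Mal, a proteolipid of compact myelin, at 0.37. The per-mouse medians overlapped, and without WT 1 the list median was -0.05. That call was lost without KO 3 or WT 1 (adjusted p up to 0.46). Lists for astrocytes (16 genes, median 0.02, adjusted p = 0.87), reactive glia (12 genes, 0.09, 0.090), microglia (15 genes, 0.15, 0.17), vascular cells (18 genes, -0.07, 0.47) and blood (3 genes, 0.04, 0.98) were not called, and 0 of their members passed over all probe sets. Adjusted over the list alone 1 passed for astrocytes, S100b at -0.37, 1 for reactive glia, B2m at 0.34, and 1 for microglia, Ly86 at 0.53. Reactive glia were called higher without WT 1 (adjusted p = 0.047) and with the mean of a gene's probe sets (0.046), within a range of 0.046 to 0.49 over all alternatives, and microglia without WT 2 (0.014, with 0.014 to 0.62). Vascular cells were called lower without KO 1 (median -0.19, adjusted p = 0.036, with 0.036 to 0.90 over all alternatives). Gjb6 gave 0.23, Lyz2 0.35, Aif1 -0.64, Vwf 0.55, Slco1a4 -0.22, S100a8 -0.40 and Alas2 0.52 without passing. Cytosolic ribosomal proteins (19 genes, median 0.00, adjusted p = 0.50) and the proteasome (25 genes, median -0.01, adjusted p = 0.87) were not called, and for the proteasome the mean (0.00) and the test were on the positive side. Rps2 was called lower (-0.38, SE 0.07, adjusted p = 0.036), the only member passing by its brightest probe set, but not without any array other than WT 3 (up to 0.19) or with each array centred on its median (0.10). No filter (0.17), no intensity trend (0.36) and the replicate block (0.14) also ended the Rps2 call, and over all alternatives its adjusted p ran from 0.015 to 0.41. Rpl22 was called lower by a dimmer probe set (-0.90, adjusted p = 0.021), while its brightest gave -0.01. Psmc4 at 0.30 and Psmb2 at 0.13 did not pass by either adjustment. Centring each array on its median raises all genes alike, and that shift alone takes the medians of the biogenesis, reactive oxygen species, synaptic vesicle, axon, ribosomal and proteasome lists above 0, so it says nothing about them.

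**Figure D3:**
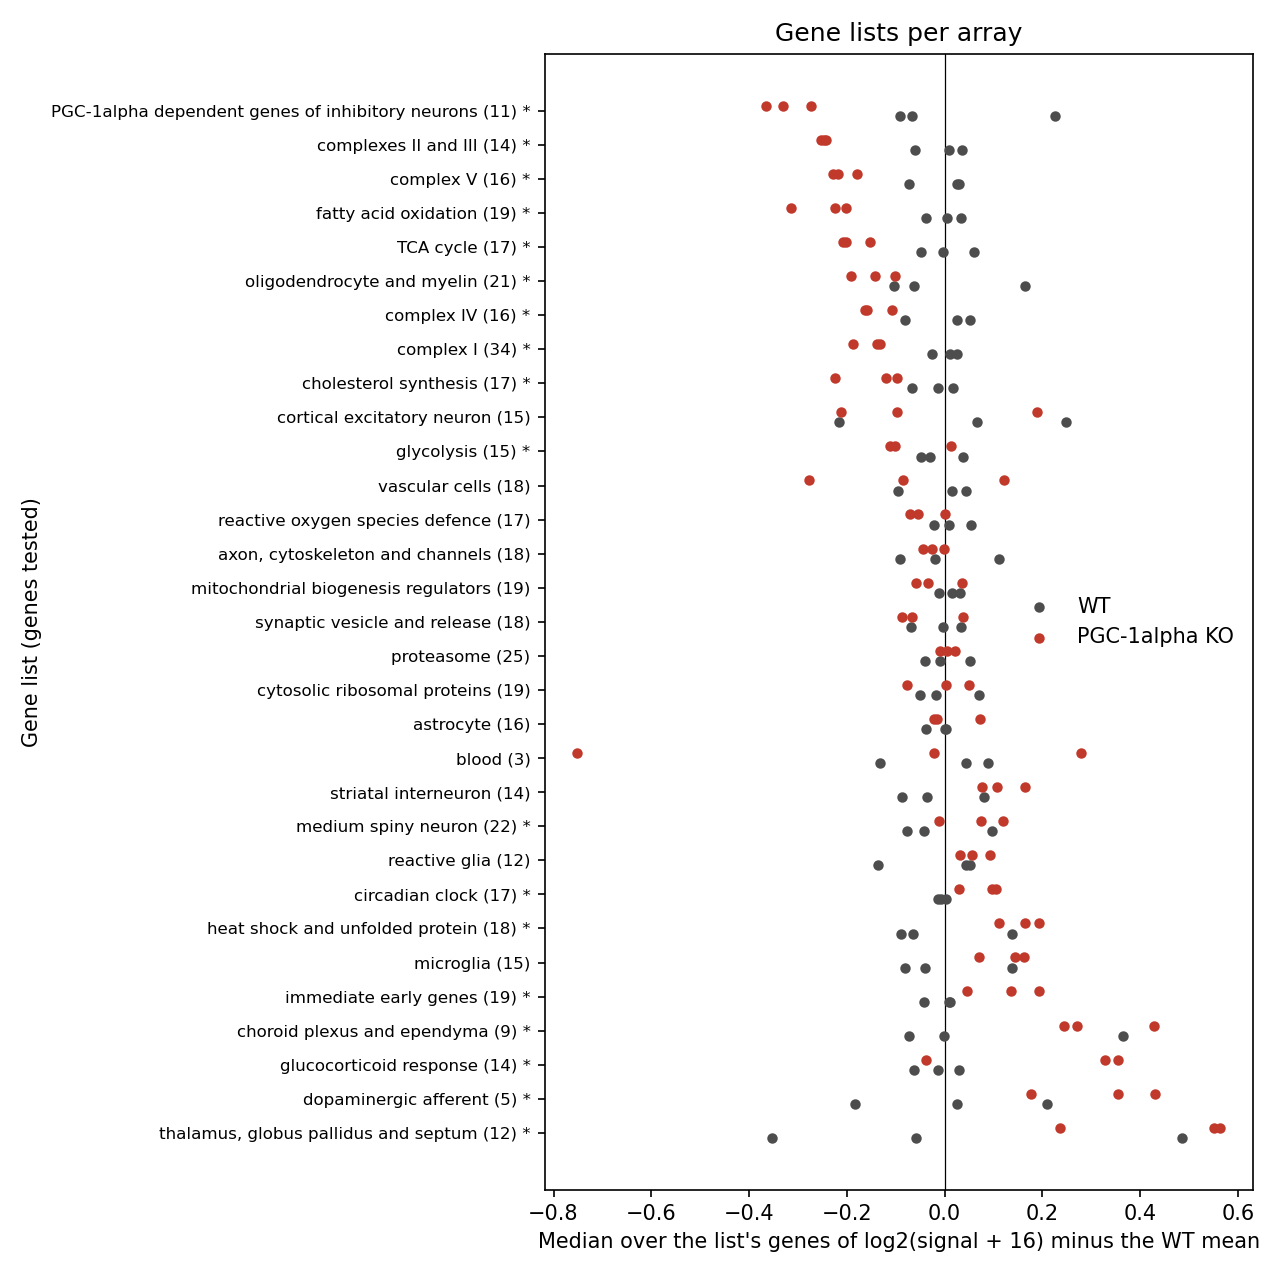
Median over the genes of each list of log2(signal + 16) minus the WT mean, 1 point per mouse, KO in red and WT in grey, with the number of genes tested in brackets and an asterisk where camera called the list at the preset correlation. For complexes II and III the KO mice lie between -0.25 and -0.24 and the WT mice between -0.06 and 0.04, while for the thalamus, globus pallidus and septum list WT 1 lies at 0.48, among the KO mice at 0.24 to 0.56.

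By camera at the preset correlation, lists for choroid plexus, for thalamus, globus pallidus and septum, and for dopaminergic afferents were called higher in KO. The cortical list was not called. Fry called only the dopaminergic afferent list among these. Across the members of all these lists only Ttr passed over all probe sets. In the choroid plexus and ependyma list all 9 genes were higher (median 0.23, camera adjusted p = 6.1e-04, adjusted p = 0.18 with an estimated correlation). Ttr, the thyroxine carrier transthyretin made by choroid plexus, rose from 1667 ± 476 to 3106 ± 533 (SD, n = 3; difference 0.91, SE 0.17, adjusted p = 0.035). The list medians of the WT mice were 0.00, -0.07 and 0.36, so WT 3 lay among the KO mice at 0.24 to 0.43, and the list median was 0.41 without WT 3 and 0.35 without KO 2. Ttr was also the only member passing over the list alone, and its call was lost without KO 1, KO 3, WT 1 or WT 2 (adjusted p up to 0.14) and with robust estimation (0.27). No filter (0.16), no intensity trend (0.30) and leaving out genes near clustered calls (0.056) also ended the Ttr call, and over all alternatives its adjusted p ran from 0.0029 to 0.54. Markers of thalamus, globus pallidus and septum were higher in 11 of 12 genes (median 0.41, camera adjusted p = 7.1e-04, adjusted p = 0.18 with an estimated correlation), and 0 passed by either adjustment. Tcf7l2 gave 0.87 and Zic1 0.74. Tcf7l2 passed without WT 1 (1.30, adjusted p = 0.017, with 0.017 to 0.72 over all alternatives). The WT mice spread widely on this list, with medians of 0.48, -0.35 and -0.06, against 0.56, 0.55 and 0.24 in KO mice, and the list median was 0.68 without WT 1 and 0.21 without WT 2. The dopaminergic afferent list was higher in 4 of 5 genes (median 0.28, camera adjusted p = 0.023, adjusted p = 0.18 with an estimated correlation). None passed over all probe sets, and 1 passed adjusted over the list alone, Ddc, aromatic amino acid decarboxylase (difference 0.69, SE 0.13, adjusted p = 0.051), followed by Th at 0.49. Th, which read 45.5 ± 6.8 in WT, also belongs to the striatal interneuron list. These are transcript levels, and whether the afferents changed was not tested. Ddc passed with each array centred on its median (0.042), an offset of 64 (0.045), the filter at the 60th percentile (0.048), robust estimation (0.045) and the replicate block (0.033), and ran from 0.033 to 0.47 over all alternatives. The per-mouse medians of the list overlapped, and its median was 0.49 without WT 3 and 0.44 without KO 2. The call of the list was lost without KO 3, WT 2 or WT 3 (adjusted p up to 0.091) and with the filter at the 60th percentile (0.18), within a range of 0.011 to 0.18 over all alternatives. Cortical excitatory neuron markers were not called (15 genes, median -0.14, adjusted p = 0.31), with Lmo4 at -0.30 and Lmo3 at -0.22 and 0 passing by either adjustment. They were called lower without KO 3 (adjusted p = 0.0054) or without WT 3 (median -0.22, adjusted p = 0.036), within a range of 0.0054 to 0.92 over all alternatives.

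Stress and activity genes were mostly higher in KO. The heat shock and unfolded protein list was called higher with 14 of 18 genes higher (median 0.15, camera adjusted p = 8.2e-05, adjusted p = 0.30 with an estimated correlation). Of its members 5 passed adjusted over the list alone and 0 over all probe sets. Hspb1 gave 0.49 and Hspa5, the chaperone BiP, 0.26. The groups overlapped on this list: WT 1 at 0.14 lay among the KO mice at 0.11 to 0.19, and WT 2 and WT 3 lay at -0.06 and -0.09. Immediate early genes were called higher with 14 of 19 higher (median 0.16, camera adjusted p = 0.0011, adjusted p = 0.17 with an estimated correlation). Of these genes 4 passed adjusted over the list alone, among them Fosl2 (0.47) and Egr3 (0.26), and 0 over all probe sets. Fosl2 lies near Ppargc1a or near clustered calls. Without such genes the list stayed called, with its highest adjusted p over all alternatives (camera, 0.019). The list median was 0.08 without KO 1, 0.10 without WT 3 and 0.11 without WT 1. The glucocorticoid response list was called higher, with 10 of 14 genes higher (median 0.27, camera adjusted p = 0.0029, adjusted p = 0.30 with an estimated correlation). Over the list alone 5 passed higher and 2 lower, but its only member called over all probe sets, Pdk4, went the other way. Pdk4, the kinase that switches off pyruvate dehydrogenase, fell from 158 ± 24 to 79.3 ± 17 (SD, n = 3; difference -0.87, SE 0.16, adjusted p = 0.039), a call lost without any array but KO 3 (up to 0.17). No filter (0.13), no intensity trend (0.22), the replicate block (0.063) and leaving out genes near clustered calls (0.059) also ended the Pdk4 call, and over all alternatives its adjusted p ran from 0.027 to 0.43. The per-mouse medians of the list overlapped, and its median was 0.18 without WT 1. The call of the list was lost without KO 3 (adjusted p = 0.069). Circadian clock genes were higher in 12 of 17 (median 0.12, camera adjusted p = 0.030, adjusted p = 0.18 with an estimated correlation), with 0 passing by either adjustment and Cry1 at 0.44 and Per1 at -0.30. Without KO 3 the list median was 0.08. That call was lost without KO 2, WT 1 or WT 2 (adjusted p up to 0.084), without the intensity trend (0.063) and with the mean of a gene's probe sets (0.38), within a range of 0.016 to 0.38 over all alternatives.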

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

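The alternative without genes near clustered calls was chosen after seeing the data, the rest before. The main counts were 48 higher and 79 lower probe sets and 18 lists. Higher and lower counts were 17 and 35 with no filter on dim probe sets (3488 at an unadjusted p under 0.05), 9 and 16 for eBayes without trend, 74 and 120 at an adjusted p under 0.1, and 18 and 31 without genes near clustered calls. The plain equal-variance test called 0 higher and 0 lower, with 2247 at an unadjusted p under 0.05, and left Ppargc1a at -1.93 with an adjusted p of 0.26, against 1.1e-05 to 6.5e-03 in its other alternatives. With 4 residual degrees of freedom that test borrows no spread between probe sets; why the filter and the trend matter as much was not tested. Both scalings, both offsets, the filter at the 60th percentile and robust estimation gave 39 to 59 higher and 57 to 83 lower. Leaving out each array in turn gave 22 to 44 higher, 40 to 62 lower and 15 to 17 lists, with fewer arrays in each fit. With an estimated correlation 0 lists were called and by fry 7. The replicate numbers do not pair the mice: same-number deviations correlated at -0.009, -0.035 and 0.017. With the replicate block there were 36 higher, 64 lower and 18 lists, and 86 of the 127 calls remained. Among named genes the block ended the calls for Ramp1, Acadl, Sod2, Rps2 and Pdk4, gave one for Ddc and changed no other. Of 1376 values of named genes under these alternatives, 1217 kept their side of the threshold, 150 lost it, 9 gained it and 0 reversed while called. Of 496 list medians, 467 kept their side, 22 lost it and 7 gained it. Among named genes and list medians together, 22 values not called in either fit changed sign.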

Other observations

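Some mitochondrial and peroxisomal genes outside the lists fixed in advance were called lower in KO striatum by limma; the genes and the 4 groups in these first paragraphs were chosen after their values were seen, so the counts describe them and test nothing. Among peroxisomal genes 22 of 33 were lower (median -0.11), and Nudt19 (-0.80) and Ech1 (-0.58) were called, beside Phyh from the fixed lists. Among mitochondrial carriers 16 of 22 were lower (median -0.10). Slc25a5, an ADP/ATP exchanger, was called lower by 1 probe set (-0.75, adjusted p = 0.0045), and its other probe sets, from -0.48 to -0.18, did not pass. The pyruvate carrier gene Mpc1 gave -0.31 and the ADP/ATP exchanger gene Slc25a4 -0.25, neither passing. Glutamate dehydrogenase, Glud1, was called lower by 1 probe set (-0.57, adjusted p = 0.0045). Glud1 and Ech1, and Glo1 below, have a called gene as neighbour, so what is said of such genes further down applies to them. Of the mitochondrial ribosomal proteins 52 of 73 were lower (median -0.06), with 0 called by limma and 2 at an unadjusted p under 0.05.

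Of the GABA-A receptor subunits, 7 of 9 were higher (median 0.07), but Gabrb1 and Gabra3 by only 0.004 and 0.0004. Gabra2, the alpha2 subunit, was called higher by 3 probe sets, at 0.78, 0.83 and 0.84. No other member was called by its brightest probe set. Gabra2 lies near Ppargc1a, and Gabra4 (0.18), Gabrg1 (0.11) and Gabrd (-0.03) lie near Ppargc1a or near clustered calls. What is said of such genes further down applies to all of them. Glo1, which detoxifies methylglyoxal, was called lower by 4 probe sets, from -0.64 to -1.07. Among 156 families of at least 10 genes that share a symbol prefix, 3 were called lower by camera, Ndufb, Ndufa and Cox, with an adjusted p of 0.99 for each with an estimated correlation. Ndufb and Ndufa largely repeat genes of the complex I list, and Cox overlaps the complex IV list. These calls therefore add no separate evidence to those lists.

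The splits of the arrays, the RNA integrity test and the share of calls near Ppargc1a were chosen before the result was seen, and the other tests in this part after it. The first pattern is the set of called probe sets. Of the 10 splits of the 6 arrays into 3 and 3, only the real split, 1 of 10, gave as many as 127 calls. The highest of the others gave 1, and 10 splits are too few for a share under 0.05. The other splits mix the genotypes on both sides, so a genotype difference widens the spread within their groups and lowers their calls. Their counts therefore do not show how many calls arise without a difference. A difference in RNA integrity is argued against by the 3'/5' log2 ratio of beta-actin, which differed by -0.0286 with overlapping ranges. Variants of the donor strain carried along with the targeted gene remain open for genes near it: probe sets within 20 Mb of Ppargc1a, from Gabra2, Atp8a1 and Uchl1, were 4.47 times as common among called as among tested ones, but by genes Fisher's exact p was 0.056 (two-sided), and 78 of 81 called genes lie elsewhere. Segments of a second strain, also on other chromosomes, may account for part of the calls. Of the called genes 32 had a called neighbour within 2 Mb, against a median of 15 in 10000 random draws (highest 39, one-sided permutation p = 9.0e-04). This count left out Ppargc1a but not the genes near it, so Uchl1 and Atp8a1 are among the 32. Cdhr1 and Ghitm, Gnb1 and Mxra8, and Glud1, Mapk8 and Ldb3 were such neighbours. Sdc4, Adi1, Sox11, Mapk14, Efhd2, Slc2a5, Vamp3, Rps2, Rpl22, Acadl, Ech1 and Glo1 were also among the 32. Fosl2, Sdhb, Mag and Psmc4, named above but not called, also lie near Ppargc1a or near clustered calls. Without all such genes the same 18 lists stayed called by camera at the preset correlation. Co-regulation of neighbours stays open.

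The second pattern is the small fall across the respiratory chain. For lists, 1 of 10 splits, the real one, called as many as 18, and the highest other split called 11, so camera at the preset correlation calls many lists in mixed splits too; 10 splits are too few here too. All 4 respiratory chain lists were also called in 3 of the 9 other splits, where the size of the chain's median was 0.11 at most. Every other split mixes the genotypes unevenly and so keeps part of any genotype difference. List calls in those splits therefore do not show how often camera calls lists without a difference. A difference between arrays that follows brightness is argued against, since the median of -0.18 lay below all 10000 random lists matched on brightness, the lowest at -0.05. A lower share of neurons is argued against by 58 neuronal markers with a median of 0.018 (SE 0.043). Some lists for neighbouring regions and for other cell types also had shifted medians in these mice. Thalamus, globus pallidus and septum markers had a median of 0.41, choroid plexus and ependyma 0.23, and oligodendrocyte and myelin -0.17. On each of these lists the per-mouse medians of KO and WT overlapped. A difference in dissection was not tested for the chain and stays open, as do lower expression within cells, a shift between cell types and chance.

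The third pattern is Ttr, higher in KO by 0.91. More choroid plexus in the KO dissections is a possible explanation: the other 8 markers of choroid plexus and ependyma had a median of 0.22, all higher, and 6 of them read under 100 in WT. The 2 brighter ones, Clic6 at 0.18 and Rarres2 at 0.15, lie far below Ttr and did not pass, while the dim Calml4 gave 0.58. With only 2 markers bright enough to show a rise in proportion, carry-over of choroid plexus and a change of Ttr within the striatum cannot be told apart.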
